A study of Mus musculus with 8 samples.

How the data were processed

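RNA was sequenced from 8 libraries of mouse preSC cells, 4 from polyclonal populations that received a guide RNA against Max and 4 from populations that received a control guide. Per the labels' protocols, total RNA was extracted with TRIZOL, and libraries were made from 500 ng with an NEB Ultra RNA kit. The counts per gene symbol were made by the authors before the files were deposited, by base calling with bcl2fastq 1.8.4, alignment to the mm9 genome with TopHat2 2.0.12 and counting with HTSeq 0.6.1, per the submitters' processing notes. The gene annotation and the strand setting of the counting are not given in the sources used here, and the kit is not said to mark strand, so overlapping and antisense genes cannot be told apart by strand. Genes with near-identical copies elsewhere in the genome lose reads that align to several places and are reported as uncertain. The deposited counts were used as they are. Gene symbols are those of the files, and no gene positions are given because the reference at hand (GRCm38, GENCODE) is of another build than mm9.

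The files held 23284 genes, of which 19124 had a count. Genes were kept with filterByExpr, which left 13358. Counts were scaled with TMM factors, and CPM values in the text use these factors, except for the genes under the filter and the floors, which use the plain library totals. The groups were compared in R 4.3.3 with edgeR 4.0.16, by the quasi-likelihood F test (glmQLFit with robust = TRUE) with group as the only term and Benjamini-Hochberg adjustment over all tested genes. A gene was called changed at an adjusted p under 0.05, and large changes were those of at least 2-fold. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Principal components and Pearson correlations were computed on log2 CPM with a prior count of 2.

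A set of 23 gene lists was fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The lists covered the MYC and MAX network, the PRC1.6 complex, germline and meiosis genes, serine and folate metabolism, nucleotide synthesis, ribosome biogenesis, translation factors, the amino acid stress response, glycolysis, oxidative phosphorylation, cholesterol synthesis, lysosome and autophagy, the cell cycle, CDK inhibitors with the RB and p53 pathways, neuroendocrine genes, the Notch pathway and non-neuroendocrine state, the interferon response, the hypoxia response, and markers of fibroblasts, haematopoietic cells, endothelium and other lung epithelium, and the mitochondrial genome. The 19 lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera was also run with the correlation estimated from the data, and fry was run as a test of whether the genes of a list move on balance one way, which does not compare them with other genes. None of the 13 mitochondrially encoded genes was in the files, so the mitochondrial share of counts, which had been planned, could not be computed. The share of counts in 68 replication-dependent histone genes was compared by a two-sided exact permutation test over the 70 assignments of libraries.

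The text draws its named genes from the 12 largest rises and the 12 largest falls among called genes with an average log2 CPM of at least 1 and groups that did not overlap. It leaves out 160 predicted or clone-named genes. It also draws on the network genes, Rb1, Trp53 and Rbl2, and up to 4 members with the smallest p of each other list. Aldoa, Calca, Chga, Eno1, Hk1, Insm1, Ldha, Mki67, Ncl, Pgam1 and Pgk1 fall outside that rule and were chosen after their values were seen, as were the genes under the count filter that the text names.

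The alternatives were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, the quasi-likelihood fit without robust estimation, a term for the replicate number, and leaving out each library in turn. Fits with only controls 1 and 2, with only controls 3 and 4, and with the share of reads outside exons as a term were added after the data were seen. The replicate number was not used in the reported fit because the labels do not say that equal numbers mark a shared culture. They also do not say that replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The exact interval for olfactory receptor counts and the floors cover counting error only. The intervals for the mixing shares and the share of falls treat genes as independent and leave out the spread between libraries.

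The procedure was tested on simulated counts with 4 against 4 libraries over 13270 genes. The test recovered 47.8% of 67 genes changed by 0.5 on the log2 scale, 86.6% of 67 changed by 1 and 98.5% of 66 changed by 2, and 7 of 162 calls were false. In simulated counts of 13262 genes, camera called 2 of 2 lists shifted by 0.5 and 0 of the others among 19 lists. Each gene was simulated independently of the others. The simulation therefore cannot show how often camera calls a list falsely when its genes vary together.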

Results

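RNA sequencing was performed on preSC cells, a mouse culture model of precancerous neuroendocrine lung cells. The cells came from mice carrying conditional alleles of Rb, p53 and p130 and a green fluorescent reporter of Chga, a neuroendocrine gene. Polyclonal populations, that is, cells that were not cloned from a single cell, received either a guide RNA against Max or a control guide and were selected with puromycin and expanded. MAX is the protein that pairs with MYC, MYCN and MYCL to bind DNA, and it also pairs with MNT, MGA and the MXD proteins. The comparison asked how gene expression in these cells differed once Max had been targeted. There were 4 Max knockout libraries and 4 control libraries. The depth was 14952291 to 19480947 reads counted in genes in the knockout libraries and 13711278 to 19804949 in the controls, so that 1 read corresponded to 0.0505 to 0.0729 normalised read counts in the unit CPM (counts scaled by library size). A gene with no read in a library could have had a level of up to 0.151 to 0.219 CPM (3 counts). Such limits cover counting error only. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

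Max mRNA was measured at 42.3, 42.3, 59.1 and 68.0 CPM in knockout libraries 1 to 4 and at 65.5, 70.2, 75.2 and 61.9 CPM in control libraries 1 to 4. The means were 52.9 ± 12.8 CPM in the knockout and 68.2 ± 5.75 CPM in the control (SD, n = 4 each). The difference of -0.37 on the log2 scale (SE 0.15) did not pass the threshold in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0955). It passed only when knockout library 4 was left out (-0.52, adjusted p = 0.0228). Small insertions and deletions made by Cas9 change the protein and need not lower the transcript, so the Max count is a weak check of the knockout, and the share of edited alleles was not measured here. Of the other genes in the genotype, Rb1 (0.23, adjusted p = 0.184, but 0.35 and 0.0160 without control 4, and 0.29 and 0.00770 with only controls 1 and 2) and Trp53 (0.05, adjusted p = 0.718) did not pass the threshold. Rbl2, which encodes p130, was lower in the knockout (-0.38, adjusted p = 0.0323), a call that ended in 6 of the 8 fits that each left out 1 library (adjusted p up to 0.0972).

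The Max knockout libraries differed from the controls in 3084 of 13358 tested genes (23.1%). In limma's camera test with a preset correlation, 8 of 19 gene lists stood apart from other genes, but none did with an estimated correlation (adjusted p = 0.521 for the hypoxia response and 0.60 for the other 7). The lists for glycolysis, the hypoxia response and the interferon response were lower, and those for serine and folate metabolism, nucleotide synthesis, the amino acid stress response, cholesterol synthesis and the cell cycle were higher, although at least 10 members of each did not pass the threshold singly or moved the other way. Tex101, which encodes a surface protein of male germ cells, fell 11.6-fold to 1.88 ± 0.431 CPM, and the iron exporter gene Slc40a1 rose from 10.9 ± 2.61 to 40.7 ± 3.55 CPM (SD, n = 4 each).

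By edgeR's quasi-likelihood test, 1457 genes were higher and 1627 lower in the knockout at an adjusted p under the threshold of 0.05. Changes of at least 2-fold were mostly falls, with 500 genes lower and 155 higher. With upper-quartile scaling, 1160 genes were higher and 1965 lower, which raised the share of falls from 52.8% to 62.9% and moved the median of all genes to -0.05 on the log2 scale. For 2773 of the 3084 genes, the 4 knockout values did not overlap the 4 control values. Over all tested genes, 3531 (26.4%) did not overlap, where chance gives 2.86%. The biological coefficient of variation between libraries of a group was 12.1%. The 4 control libraries were less alike than the 4 knockout libraries. Pearson correlations of log2 CPM across genes were 0.993 to 0.995 among knockout libraries, 0.973 to 0.995 among controls and 0.963 to 0.982 between the groups. Controls 3 and 4 also had more reads outside annotated exons (23.3% and 23.4%) than controls 1 and 2 (18.5% and 18.6%), while the knockout libraries had 20.5% to 21.5%. With only controls 1 and 2 kept, 6068 genes passed the threshold, and with only controls 3 and 4 kept, 2810 did. These fits were chosen after the data were seen.

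**Figure D1:**
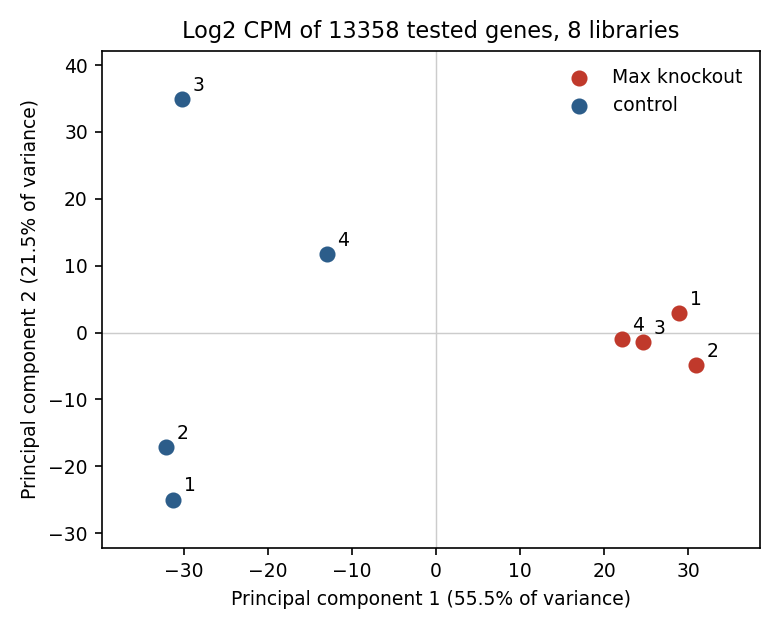
Principal components of log2 CPM over the 13358 tested genes, 1 point per library, with the library number beside it and the share of variance on each axis (55.5% and 21.5%). Knockout libraries (red) lie at 22.1 to 30.9 on component 1 and controls (blue) at -32.1 to -13.0. Controls 1 and 2 lie at -25.0 and -17.1 on component 2 and controls 3 and 4 at 34.9 and 11.7.

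Among the 13 genes of the MYC and MAX network, 3 rose, 2 fell and 8 did not pass the threshold, with the same counts when adjusted over the list alone. Over the fits that each left out 1 library, 1 to 3 rose and 1 to 3 fell, with 1 rise without knockout library 1 or 3 or control 1 or 2. Mnt, which encodes a repressor that pairs with MAX, rose from 82.8 ± 16.8 to 131 ± 16.4 CPM (SD, n = 4 each; log2 fold change 0.66, SE 0.14, adjusted p = 0.00525, edgeR). Mxd1, another MAX-dependent repressor gene, fell by 0.41 on the log2 scale. With only controls 3 and 4 kept, the rise of Mnt was 0.42. Mlx (0.24) and Mlxip (0.26) rose and Mycn (-0.44) fell by small amounts. Leaving out 1 library ended the call of Mlx in 4 of 8 fits, of Mlxip in 6 and of Mycn in 2 (adjusted p up to 0.0637, 0.130 and 0.0648). Myc was at 27.4 ± 1.81 CPM in the knockout and 71.6 ± 70.2 CPM in the control, and its difference of -1.37 (SE 0.59) did not pass the threshold (adjusted p = 0.136). Control 3 alone held 176 CPM of Myc, and without it the difference was -0.43 (adjusted p = 0.0891). Control 4, at 23.7 CPM, lay below all 4 knockout libraries (26.3 to 30.1 CPM). Without this control the fall of Myc passed the threshold in edgeR's test (-1.67, adjusted p = 0.0289). It also did so with only controls 1 and 2 (-0.66, adjusted p = 7.09e-06), the most alike pair of controls (Pearson correlation 0.995). Both fits leave out the control that goes against a fall. Mycl1, the L-Myc gene, was at 71.8 ± 4.37 and 81.2 ± 9.80 CPM (adjusted p = 0.190). The network as a group did not differ from other genes in limma's camera test (adjusted p = 0.873).

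The largest rise among the genes named by the fixed rule was that of Sox3, a transcription factor gene, from 0.647 to 5.58 CPM (3.10 on the log2 scale, SE 0.27). Several of the next largest rises belonged to genes of the cell surface and of cell contacts. These were the nectin gene Pvrl4 (2.06), Lad1, whose product is part of anchoring filaments (2.27), and the membrane protease gene Tmprss2 (1.87). Ion transport genes were also present, namely Kcnj1 (2.21), Slc40a1 (1.90) and Trpv3 (1.76). Itpkb (1.99), Myh7 (1.83), Cnksr1 (1.82) and the hedgehog-binding gene Hhip (1.81) rose as well. All 12 rises kept their call in each fit that left out 1 library, by edgeR's test with adjusted p = 0.00662 or lower in the full data. The rise of Trpv3 was 2.74 with only controls 1 and 2 kept and 1.13 with only controls 3 and 4 kept.

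The 12 largest falls included Tex101, with a log2 fold change of -3.54 (SE 0.15) and the smallest adjusted p of all genes (3.51e-07, edgeR). Tex101 lay between 1.34 and 2.35 CPM in all 4 knockout libraries and at 21.1 CPM or more in all 4 controls. P4ha2, a subunit of the enzyme that hydroxylates proline in collagen, fell from 28.8 ± 8.18 to 4.00 ± 0.473 CPM (SD, n = 4 each; -2.85). The signalling genes Rapgef5 (-3.28) and Chn1 (-3.14), the RNA-binding gene Rbm24 (-3.02) and the transthyretin gene Ttr (-2.95) also fell, although Ttr fell by 1.57 with only controls 3 and 4 kept. Control 3 set the size of the remaining falls. Without it, Stmn4 went from -5.12 to -2.87, Rbfox3 from -3.41 to -1.62, Igfbp2 from -3.30 to -2.41, Mpdz from -3.22 to -1.42, Ebf3 from -3.03 to -2.01 and Evc from -2.98 to -1.77, and all 6 stayed past the threshold. Leaving out another library ended the call of Stmn4 in 4 fits, of Rbfox3 and Mpdz in 5 each and of Evc in 2 (edgeR adjusted p up to 0.0979, 0.120, 0.110 and 0.0583). Stmn4, Rbfox3, Mpdz and Ebf3 were also not past the threshold with only controls 3 and 4 kept (adjusted p from 0.0583 to 0.0703) or with limma-voom (0.0626 to 0.131). These genes and Evc were not past it without the count filter either (0.0670 to 0.143).

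**Figure D2:**
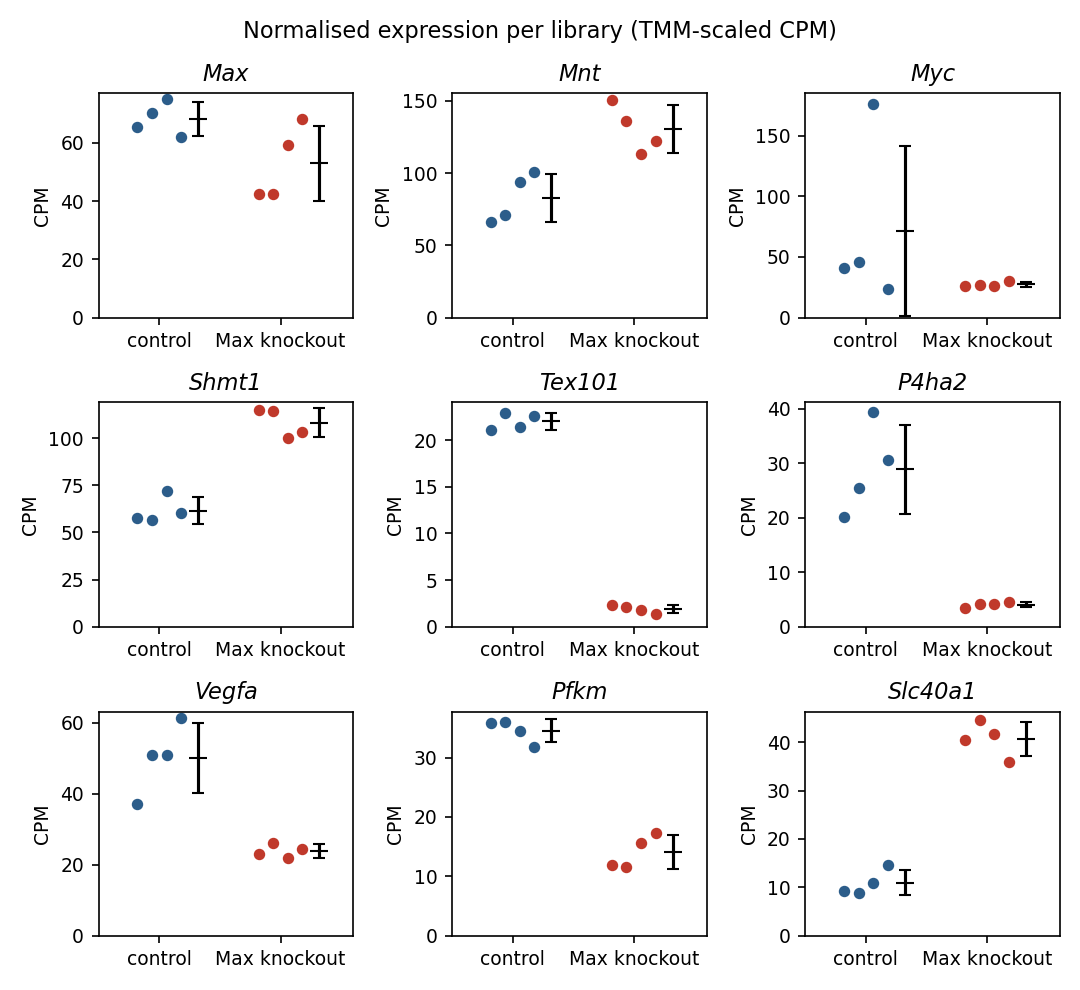
TMM-scaled CPM of 9 genes in each library (points, controls blue and Max knockout red, in library order) with the group mean and SD (black bars, n = 4 each) on axes that start at 0. Tex101 lies at 1.34 to 2.35 CPM in the knockout against at least 21.1 CPM in the control, the Max values of the groups overlap, and the Myc mean of the controls rests on control 3 (176 CPM).

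In the serine and folate list, 5 of 26 tested genes rose and 1 fell, also when adjusted over the list alone. Without control 3, 12 rose and 1 fell, and with only controls 1 and 2 kept, 14 rose and 3 fell. Only 3 rose when any 1 knockout library or control 2 was left out, and with only controls 3 and 4 kept. The serine hydroxymethyltransferase gene Shmt1 rose from 61.6 ± 7.24 to 108 ± 7.59 CPM (SD, n = 4 each; 0.82). The folate dehydrogenase gene Aldh1l2 (0.68) and the neutral amino acid transporter gene Slc1a5 (0.50) rose, whereas Amt, of the glycine cleavage system, fell (-1.55). With only controls 3 and 4 kept, the rise of Aldh1l2 was 0.42. The list was higher as a group in camera (adjusted p = 0.0276, but adjusted p = 0.60 with an estimated correlation). Its call ended without control 1 (0.0634), control 2 (0.0696) or control 4 (0.0510), and with only controls 3 and 4 (0.262). In the nucleotide list, 7 of 28 genes rose and 1 fell (8 and 1 adjusted over the list alone), including the purine genes Adss (0.54) and Guk1 (0.37) and, downward, Impdh2 (-0.53). The pyrimidine synthesis gene Cad rose by 0.37 on the log2 scale, a call that ended in 3 of the 8 fits without 1 library (edgeR adjusted p up to 0.0589) and with only controls 3 and 4 kept (0.20, adjusted p = 0.108). Camera gave an adjusted p = 0.0162 for this list (adjusted p = 0.60 with an estimated correlation, 0.0602 without control 1 and 0.320 with only controls 3 and 4). Without control 3, 12 of its genes rose and 1 fell, and 2 or 3 rose when any 1 knockout library, control 1 or control 2 was left out.

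Of 27 tested genes of the amino acid stress response, which is driven by ATF4, 5 rose and 2 fell (7 and 2 adjusted over the list alone). The tRNA synthetase genes Wars (0.37) and Eprs (0.43) and the stress gene Nupr1 (0.76) rose. Ddit3, which encodes CHOP, fell from 40.8 ± 9.38 to 22.6 ± 1.76 CPM (SD, n = 4 each; -0.85), opposite to the list. The list had a median of 0.32 and a camera adjusted p = 0.00696 (adjusted p = 0.60 with an estimated correlation). Without control 3, 18 of its genes rose and 3 fell, and without any 1 knockout library, 4 rose and 1 fell. With only controls 1 and 2 kept, 21 rose and 3 fell, and with only controls 3 and 4 kept, 5 rose and 1 fell and the list was not past the threshold (adjusted p = 0.0946). Of 23 cholesterol synthesis genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone). Mvd (0.51), Fdft1 (0.49) and Hsd17b7 (0.70), which encode enzymes of the sterol pathway, rose. Camera gave an adjusted p = 0.0102 for cholesterol synthesis (adjusted p = 0.60 with an estimated correlation and 0.0946 with only controls 3 and 4 kept). Without control 3, 11 of these genes rose and 1 fell, and with only controls 3 and 4 kept, 4 rose and 0 fell. Hmgcs1 was listed at 0 in every library, which is uncertain and not read as absence, since the annotation used for counting is not given.

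Of 22 glycolysis genes, 10 fell and 1 rose, also when adjusted over the list alone. Without knockout library 3, 6 fell, and without control 2, none rose. The muscle phosphofructokinase gene Pfkm fell from 34.5 ± 1.97 to 14.1 ± 2.84 CPM (-1.29), and the lactate exporter gene Slc16a3 fell from 94.8 ± 23.8 to 48.6 ± 7.35 CPM (-0.96; SD, n = 4 each). The aldolase gene Aldoc (-1.13) and the enolase gene Eno2 (-0.59) fell as well, whereas the hexokinase gene Hk1, singled out after its values were seen, rose (0.30). Counts of Aldoa, Ldha, Pgk1, Pgam1 and Eno1, which were also lower, are less certain because these genes have near-identical copies in the genome. The glycolysis list had a median of -0.28 and a camera adjusted p = 0.00696 (adjusted p = 0.60 with an estimated correlation). With only controls 1 and 2 kept, its median was -0.17 and the call ended (adjusted p = 0.0921). Of 16 hypoxia-response genes, 6 fell and none rose (8 and 0 adjusted over the list alone), and 9 fell and 1 rose without control 3. P4ha1, another collagen hydroxylase subunit, fell from 51.0 ± 2.93 to 17.9 ± 2.32 CPM (-1.51), and the angiogenic factor gene Vegfa fell from 50.0 ± 9.82 to 23.8 ± 1.88 CPM (-1.07; SD, n = 4 each). The mitochondrial protein gene Higd1a also fell (-0.73). The hypoxia list was lower as a group in camera (adjusted p = 0.00824, but adjusted p = 0.521 with an estimated correlation), and its median was -0.31. With the preset correlation it stayed past the threshold with either pair of controls, with a median of -0.37 for controls 1 and 2 (0.0241) and of -0.12 for controls 3 and 4 (0.0164).

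Of 18 tested interferon-response genes, 7 fell and none rose (8 and 0 adjusted over the list alone). Usp18, which removes the ubiquitin-like protein ISG15, fell to 7.66 ± 0.582 CPM (SD, n = 4; -1.32, SE 0.20), and by 0.86 on the log2 scale with only controls 3 and 4 kept. The immunoproteasome subunit gene Psmb9 (-0.56), the signalling gene Stat2 (-0.39) and the interferon-induced gene Ifit1 (-1.21) fell. The call of Stat2 ended without knockout library 2 (edgeR adjusted p = 0.0508), and that of Ifit1 in 4 of the 8 fits without 1 library (up to 0.0584) and with only controls 3 and 4 kept (-0.46, 0.224). The list had a median of -0.39 and a camera adjusted p = 0.0276 (adjusted p = 0.60 with an estimated correlation). Its call ended without control 1 (0.0634), without control 2 (0.0715) and with only controls 3 and 4 kept (0.262), when 1 gene rose and 2 fell. From 2 to 4 of its genes fell without knockout library 1, 2 or 3 or control 2, and 9 fell without control 3 or control 4. With only controls 1 and 2 kept, 14 of 21 tested genes fell and 0 rose (median -0.65, camera adjusted p = 0.000309 with the preset correlation).

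**Figure D3:**
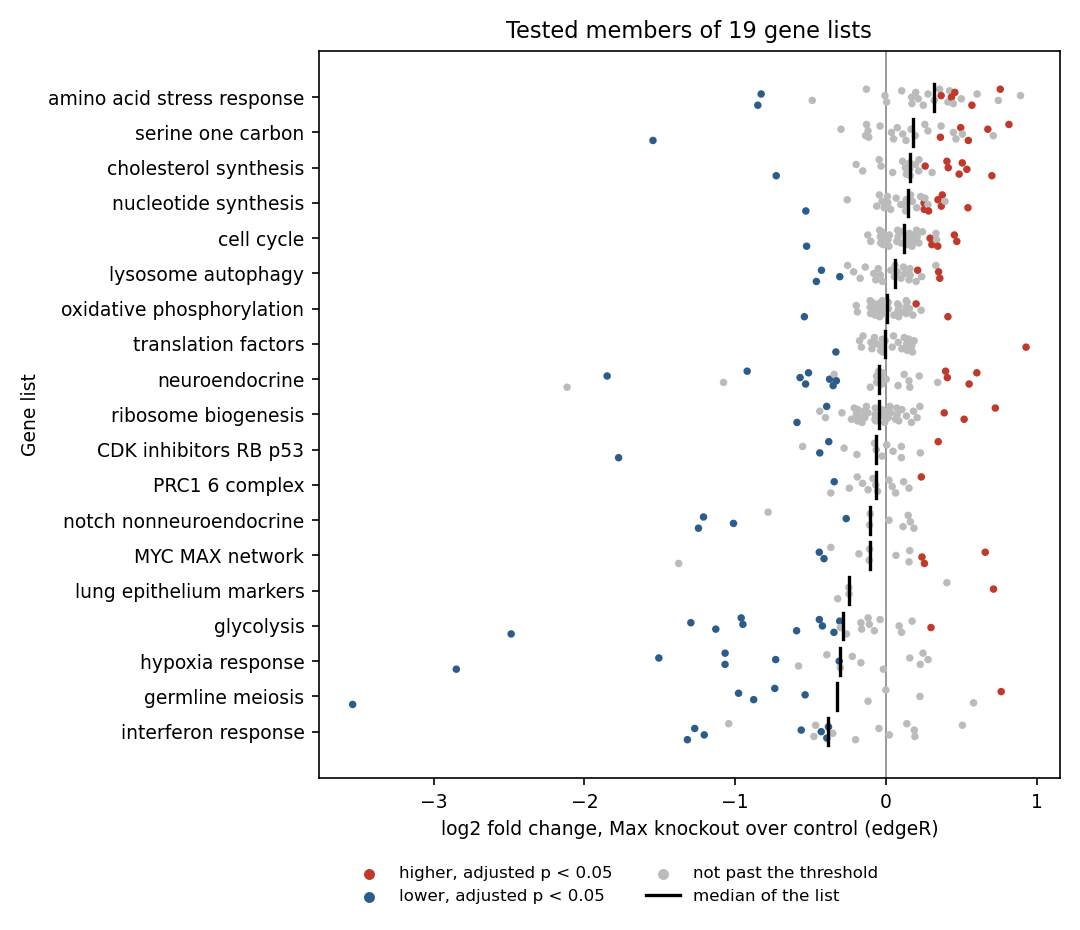
Log2 fold change (Max knockout over control, edgeR, n = 4 libraries each) of the tested members of 19 gene lists, 1 point per gene, with list medians as black bars. Red and blue points passed the threshold upward and downward, and grey points did not. Medians run from -0.39 for the interferon response to 0.32 for the amino acid stress response.

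Of 36 cell cycle genes, 5 rose and 1 fell (4 and 1 adjusted over the list alone). The rises included the replicative helicase genes Mcm3 (0.47) and Mcm2 (0.34). E2f1 rose by 0.45 on the log2 scale, a call that ended in 4 of the 8 fits without 1 library (edgeR adjusted p up to 0.0684). It was 0.73 with only controls 1 and 2 kept and 0.21 (adjusted p = 0.0911) with only controls 3 and 4 kept. Cdc25a, a phosphatase gene that promotes S phase entry, fell from 82.2 ± 14.2 to 57.0 ± 1.83 CPM (SD, n = 4 each; -0.53), and by 0.33 on the log2 scale with only controls 1 and 2 kept. The proliferation marker Mki67 was at 995 ± 61.5 CPM in the knockout and 1014 ± 37.3 CPM in the control. Camera called the cell cycle list higher (median 0.12, adjusted p = 0.0276), but not with an estimated correlation (adjusted p = 0.60), without knockout library 4 (0.0648) or with only controls 1 and 2 (0.0829). Of its genes, 8 rose without control 3, and 2 rose without knockout library 1, 2 or 4 or control 2. Among 15 genes of the CDK inhibitors and the RB and p53 pathways, 1 rose and 3 fell, also when adjusted over the list alone, and camera did not call the list (adjusted p = 0.332), whereas fry called it lower (adjusted p = 0.00943). Only 1 gene fell without knockout library 1, control 1 or control 2, and 5 fell without control 3. There were 3 rises and 6 falls with only controls 1 and 2 kept, and 0 and 1 with only controls 3 and 4 kept. Cdkn1c, which encodes the CDK inhibitor p57, fell from 54.1 ± 13.4 to 15.8 ± 2.14 CPM (SD, n = 4 each; -1.77).

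Of 29 tested neuroendocrine genes, 4 rose and 8 fell (5 and 8 adjusted over the list alone), and camera did not call the list (adjusted p = 0.530), whereas fry, which asks whether genes of a list move on balance one way, called it lower (adjusted p = 0.0457). Only 2 rose without knockout library 1, 2 or 3 or control 2, and 11 fell without control 4. Keeping only controls 1 and 2 gave 8 rises and 11 falls. The peptide gene Grp fell from 4.43 ± 1.12 to 1.21 ± 0.465 CPM (SD, n = 4 each; -1.85), and the secretory granule genes Chgb (-0.37) and Scg5 (-0.33) fell, while the synaptic gene Snap25 rose (0.55, or 0.35 with only controls 3 and 4 kept). The transcription factor gene Insm1 (701 ± 83.0 against 700.2 ± 65.7 CPM, adjusted p = 0.990) did not pass the threshold in edgeR's test, nor did Chga (adjusted p = 0.709). Neurod1, another transcription factor gene of the list, lay under the count filter in the full data and was not tested. Its means were 0.0710 CPM in the knockout and 1.30 CPM in the control, from 89 reads over all libraries (highest library 2.41 CPM). Calca, a neuropeptide gene, was at 1980 and 1783 CPM in controls 1 and 2, at 399 and 467 CPM in controls 3 and 4, and at 549 ± 30.9 CPM in the knockout (SD, n = 4; adjusted p = 0.164). Of 12 tested genes of the Notch pathway and non-neuroendocrine state, 4 fell and none rose, also when adjusted over the list alone, and 2 fell without knockout library 2, 3 or 4 or control 1. With only controls 3 and 4 kept, 2 rose and 3 fell and the median turned from -0.11 to 0.04, and with only controls 1 and 2 kept, 2 rose and 6 fell (median -0.28). The Notch ligand gene Jag1 fell from 18.6 ± 1.27 to 7.88 ± 1.40 CPM (-1.24) and Notch2 fell from 6.99 ± 1.72 to 3.02 ± 0.327 CPM (-1.21; SD, n = 4 each). Hes5 (-1.01) and Hey1 (-0.26) fell too, but their calls ended in 4 and 5 of the 8 fits without 1 library (edgeR adjusted p up to 0.0901 and 0.107). The Notch list was not called by camera (adjusted p = 0.332) and was called lower by fry (adjusted p = 0.0321).

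Germline and meiosis genes were examined because MAX and its partner MGA belong to the PRC1.6 repressor complex, which silences such genes in embryonic stem cells. Of 39 listed genes in the data, 29 lay under the count filter, among them Ddx4, Dazl, Tdrd1 and Sycp3, and none of the 29 exceeded 0.959 CPM in any library. Of the 10 tested, 5 fell and 1 rose, also when adjusted over the list alone, and without control 4, 2 rose. Beside Tex101, the falls included Zcwpw1 (-0.88) and Cpeb1 (-0.98), and Syce2, a synaptonemal complex gene, rose from 59.7 ± 6.71 CPM (SD, n = 4) by 0.76 on the log2 scale (SE 0.10). Camera did not call the germline list (adjusted p = 0.110), except without knockout library 2 (adjusted p = 0.0484), and fry called it lower (adjusted p = 0.00572). Of 15 genes of the PRC1.6 complex itself, Pcgf6 rose (0.23) and Yaf2 fell (-0.34), neither passed when adjusted over the list alone, and camera did not call the list (adjusted p = 0.530). Both calls ended in 6 of the 8 fits without 1 library (edgeR adjusted p up to 0.149 for Pcgf6 and 0.108 for Yaf2) and with only controls 3 and 4 kept (0.14 and -0.12, adjusted p = 0.287 and 0.355). With only controls 1 and 2 kept, Yaf2 was at -0.54, and without control 3, 2 genes of the complex fell.

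Of 40 ribosome biogenesis genes, which are common MYC targets, 3 rose and 2 fell (3 and 1 adjusted over the list alone). The counts and the direction depended on the controls, with 9 up and 2 down without control 3 (median 0.06), 3 up and 11 down without control 4 (median -0.12), and 10 up and 8 down with only controls 1 and 2. Utp20 (0.73), Rrp12 (0.52) and Ltv1 (0.39) rose and Rrp9 (-0.59) fell. Nucleolin, encoded by Ncl, was at 821 ± 11.9 CPM in the knockout and 814 ± 181 CPM in the control (SD, n = 4 each). Of 25 genes on the translation factor list, Eif4ebp1, which encodes an inhibitor of translation initiation, rose (0.93) and Eif5 fell (-0.33). Without control 3, 5 rose and 1 fell, without control 4, 1 rose and 3 fell, and with only controls 1 and 2 kept, 6 rose and 5 fell. Neither passed when adjusted over the list alone, and their calls ended in 3 and 5 of the 8 fits without 1 library (edgeR adjusted p up to 0.0789 and 0.0857). The rise of Eif4ebp1 was 1.47 with only controls 1 and 2 kept and 0.53 with only controls 3 and 4 kept. Of 34 genes of oxidative phosphorylation, 2 rose and 1 fell (1 and 1 adjusted over the list alone), with Uqcrc1 at -0.54 and Sdhc at 0.41, and 4 rose without control 3. Of 28 lysosome and autophagy genes, 3 rose and 3 fell, also when adjusted over the list alone, including Ctsz (-0.43) and Npc2 (-0.46), which fell, and 1 rose without knockout library 2, 3 or 4. Against controls 1 and 2 alone, 4 lysosome and autophagy genes rose and 8 fell, and 4 genes of oxidative phosphorylation rose and 5 fell. Camera called none of these 4 lists (adjusted p = 0.873, 0.530, 0.530 and 0.524). The translation list had a median of -0.01 but a mean of 0.04.

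Of 12 fibroblast markers, 3 were tested, of which Dcn rose (0.77, or 0.45 and 1.18 with either pair of controls) and Pdgfra fell (-2.37, to 0.260 CPM). Col1a1, Col1a2 and Col3a1 did not exceed 0.404 CPM in any library, whereas Col5a1, also under the filter, reached 1.67 CPM. Without the count filter, 1 of 11 fibroblast markers rose and 3 fell, with a median of -1.30 (camera adjusted p = 0.0712). Of 12 haematopoietic markers, only Cd68 (3.22 and 4.24 CPM in knockout and control) and Coro1a (74.9 and 76.7 CPM) were tested, and neither passed the threshold (adjusted p = 0.299 and 0.776, edgeR). Of 10 endothelial markers, Vwf was abundant in both groups and rose from 362 ± 73.4 to 635 ± 50.1 CPM (SD, n = 4 each; 0.81), whereas Pecam1 was at 0.618 and 0.805 CPM and Cdh5 did not exceed 0.219 CPM. Of 13 markers of other lung epithelial cells, 5 were tested and only Hopx rose (0.71), a call that ended in 7 of the 8 fits without 1 library (edgeR adjusted p up to 0.143) and when adjusted over the list alone, and its value was 0.46 with only controls 1 and 2 kept. That list had a median of -0.25 (0.12 with only controls 3 and 4 kept, when 2 genes rose), a mean of 0.06 and a camera adjusted p = 0.873. Histone genes of the replication-dependent clusters took 0.0460% ± 0.00400 of counts in the knockout and 0.0460% ± 0.0152 in the control (exact permutation test, two-sided, n = 4 each, p = 1, where 4 against 4 libraries can reach 0.0286). Controls 1 and 2 had 0.0581% and 0.0602%, and controls 3 and 4 had 0.0318% and 0.0342%.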

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

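Of the tests in this part, both tests of genomic DNA, both tests of mixed RNA and of the glycolysis and hypoxia lists without controls 3 and 4 were chosen only after the result was seen.

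Among 238 groups of 4 values examined, 16 held a library far from the other 3, where chance alone gives about 1 in 20 (11.9). Of the 16, control 3 was the distant library in 7. Most groups came from named genes, which include the 12 largest falls, and a single high control enlarges a fall. Igfbp2, Evc, Stmn4, Mpdz and Rbfox3 were among those falls, so the tally partly restates that choice. The chance figure does not allow for it. Control 3 was highest for Myc (175.9 CPM, others up to 45.9), Igfbp2 (41.9 CPM, others up to 10.6), Evc (10.9 CPM, others up to 2.04), Stmn4 (36.2 CPM, others up to 3.01), Mpdz (15.7 CPM, others up to 1.8), Rbfox3 (13.2 CPM, others up to 2.17) and Impdh2 (226 CPM, others up to 163). Control 4 was lowest for Npc2 (39.9 CPM, others from 51.8) and for Eif5 (246 CPM, others from 320). Control 1 was lowest for Uqcrc2 (175.9 CPM, others from 180.2). Knockout library 4 was highest for Myc (30.1 CPM, others up to 26.8), Cdc25a (59.7 CPM, others up to 56.3) and Rapgef5 (0.702 CPM, others up to 0.265). Knockout library 2 was highest for Mycl1 (78.3 CPM, others up to 69.9). Knockout library 1 was lowest for Pdgfra (0.0522 CPM, others from 0.319) and Ebf3 (0.574 CPM, others from 0.83).

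Controls 3 and 4 stood apart from controls 1 and 2 in Calca and histone genes and in the share of reads outside exons. Over all tested genes, however, controls 3 and 4 were not a close pair. Control 4 correlated about equally with control 3 (0.983) and with controls 1 and 2 (0.982 and 0.983), and at 0.980 to 0.982 with knockout libraries. Genomic DNA in controls 3 and 4 is argued against for Calca and histone genes, since silent olfactory receptor genes gained 0.0442 counts per gene and library (Poisson SD 0.00603), too few to move them. For the share of reads outside exons it stays open, as counts of those silent genes, scaled by depth, were 3.22 times as high in controls 3 and 4 as in controls 1 and 2 (95% exact interval 2.33 to 4.51), with the knockout libraries between. Knockout RNA mixed into a control 4 otherwise like controls 1 and 2 is argued against as the source of this split. It leaves control 3 unexplained, and in 0 of these 3 measures did control 4 (467 CPM, 0.0342% and 23.4%) lie within the span of controls 1 and 2 and the knockout libraries. These are the measures in which the split was seen, so they say nothing on mixing beyond it. A library like control 3 with knockout RNA mixed in was not tried. For the place of control 4 nearer the knockout on the principal component of largest variance (-13.0), mixing stays open. Genes lower in the knockout gave a share of 32.6% (95% bootstrap interval over genes 13.6 to 40.3), with 28.9% of them outside any mixture. Genes higher in the knockout gave a share of 15.8% (12.3 to 21.1). However, these genes were chosen by their distance from the knockout in controls 1 to 3, without control 4. Such a choice can by itself place control 4 nearer the knockout, so the shares do not measure mixing. A different state of the cultures may also be the source, which the labels give no means to test.

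Large falls outnumbered large rises, with 500 against 155 genes. Scaling stays open. The share of falls was 76.4% under RLE scaling and 79.9% under upper-quartile scaling, but neither raised the median of all genes, so neither could have lowered the share, contrary to what was planned. A trend with GC content and transcript length is argued against as the whole cause, since it was small (SD 0.0273 on the log2 scale) and the share was 76.1% after its removal. Controls 3 and 4 did not carry the whole excess, as the share was 63.0% without them (95% interval 60.1 to 65.9), where 696 genes fell and 408 rose by at least 2-fold. The share was lower than the 76.3% of all libraries because more rises were called, and not because fewer falls were. An effect of losing MAX may also contribute, which is an untested hypothesis.

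Glycolysis and hypoxia-response genes, including Pfkm and P4ha1, were lower in the knockout by camera with the preset correlation, but neither list was called with an estimated correlation (adjusted p = 0.60 and 0.521). For the hypoxia list, the state of controls 3 and 4 as the whole cause is argued against, since without them the median was -0.37 (camera adjusted p = 0.0241 with the preset correlation). For the glycolysis list that cause stays open, since without them the median was -0.17 and the adjusted p was 0.0921. Oxygen supply or cell density may have differed between cultures, which no label records, and an effect of Max loss remains untested against it.

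Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many changed genes in edgeR's test (3084, against at most 1 in any other split). Every other split mixes knockout and control libraries on a side, which adds the group difference to the spread and leaves few calls. With only 35 splits, a chance division of the libraries cannot be excluded in this way. The splits also say nothing on whether the libraries of a group share a culture.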

How the results depend on the processing

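The fits that kept only 2 controls or used the share of reads outside exons were chosen after seeing the data, and the tests of the other alternatives were planned. Under both scaling alternatives, both filters, DESeq2, limma-voom and the fit without robust estimation, 2938 to 3479 genes changed and 591 to 767 did so by at least 2-fold. With a block for replicate number, 2532 and 637 did, and Max was at -0.39. Leaving out 1 library gave 2102 (without knockout library 2) to 3743 (without control 4) changed genes, and 596 to 834 of at least 2-fold. Max ranged from -0.52 (past the threshold, without knockout library 4) to -0.27 (without knockout library 2), the gene lists called from 5 (without control 1) to 9 (without knockout library 2), and the histone share difference from -0.00476 (without control 3) to 0.00471 percentage points (without control 2). With only controls 1 and 2 there were 6068 changed genes, 2952 of them shared with the full data, and 1104 of at least 2-fold. With only controls 3 and 4 there were 2810, 2134 of them shared, and 3 lists were called. With the share of reads outside exons as a term, 4423 changed and 683 did so by at least 2-fold. Camera with an estimated correlation called 0 lists, and fry called 8, of which 4 were among the 8 of the preset test. Fry left out serine and folate, nucleotide, amino acid stress and interferon genes and added germline, CDK inhibitor, neuroendocrine and Notch genes. Mxd4, which was not called, turned from 0.07 to -0.0239 without control 3 (its highest value without 1 library was 0.14, without control 1) and to -0.11 with only controls 1 and 2, where Mlxipl turned from -0.11 to 0.0756. Of the other values of named genes, 1978 kept direction and side of the threshold, 162 lost and 20 gained their call with direction kept, and 71 of 94 called genes kept their call whichever library was left out. The cause was not tested. The alternatives for the mitochondrial share were not run, as its genes are not in the files. Depth limits genes near 0.151 to 0.219 CPM, the level that a count of 0 allows.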

Other observations

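Of the tests in this part, all concern lists written after the largest changes had been seen, each without the genes that had prompted it.

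Epithelial genes were higher in the Max knockout. Of 41 tested genes of cell junctions, keratins and epithelial transcription factors, 33 rose and 1 fell (Itgb4, -1.34), with a median of 0.76 on the log2 scale. The desmosome gene Dsp rose from 213 to 462 CPM (1.11), the junction gene F11r to 245 CPM (0.99), and the keratin gene Krt18 from 365 to 601 CPM (0.72; means, n = 4 each). The E-cadherin gene Cdh1 (0.53) and the epithelial regulators Grhl2 (0.89), Esrp1 (0.83) and Elf3 (0.88) rose too, while Epcam (0.34, edgeR adjusted p = 0.0798) did not pass the threshold. The camera p for the group was 9.91e-17, or 2.97e-16 after adjustment over the 3 lists of this part. With an estimated correlation it was 0.0170, or 0.0510 after that adjustment, which did not pass the threshold of 0.05. With only controls 1 and 2 kept the p with the preset correlation was 2.09e-14, with a median of 0.75. These values are consistent with a shift of the knockout cells toward a more epithelial state, which is a hypothesis found and tested in the same libraries.

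Some mesenchymal regulators were lower, while the group as a whole did not pass the threshold. Zeb1 (-1.15), Snai2 (-1.09) and Zeb2 (-0.68), which repress epithelial genes, fell, but Snai1 of the same class (0.11, edgeR adjusted p = 0.840) and the N-cadherin gene Cdh2 (-0.11, adjusted p = 0.309) did not pass the threshold. The actin-binding gene Flna fell (-0.59), while Anxa1 (1.10) and Tagln2 (0.68) rose. Of 29 tested actin and mesenchymal genes, 11 fell and 2 rose, with a camera p of 0.150 (0.434 with an estimated correlation and 0.0534 with only controls 1 and 2 kept).

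Of 32 tested neuronal genes, 11 fell and 4 rose. Camk2b (-1.56) and Elavl4 (-0.66) fell, and Kif1a (0.61) and L1cam (0.90) rose. The camera p was 0.0265 (0.0397 after adjustment over the 3 lists), but 0.450 with an estimated correlation and 0.688 with only controls 1 and 2 kept, so a fall of the group stays open.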
